A study of Mus musculus with 7 samples.

How the data were processed

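The series holds 7 samples of mouse sinoatrial node from strain Sv129, taken 3 weeks after birth. RNA was extracted with TRIzol and poly-A selected before sequencing, per the labels' protocols. Tamoxifen activates the CreERT2 recombinase, which then removes floxed DNA in the cells that express it. A control and samples at 16, 20, 24 and 48 h form a time series in floxed mice with Hcn4CreERT2, and these 5 libraries were not analysed here. The day-6 pair consists of 1 library from floxed mice with Hcn4CreERT2 and 1 control library from floxed mice without Cre. The labels do not say how many mice went into a library, of which sex, or whether the control mice were given tamoxifen. The comparison therefore joins the deletion, the presence of Cre, any difference in dissection and the difference in sex that the sex-linked genes show.

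Reads were aligned with TopHat and Bowtie to mm9 and quantified with Cufflinks, per the submitters' processing notes. Versions, annotation, read length, strand setting, bias correction and the scaling between libraries are not given in the sources used here. The deposited table has 1 row per gene, with 1 value per library that was taken as FPKM (fragments per kilobase of transcript per 1e6 mapped fragments), since the column layout is that of a Cufflinks comparison, per the file headers. The authors' deposited log2 fold change, test statistic (a score), p-value, q-value and significance call stand in the same rows. The log2 fold change was checked to be the log2 of Cre over control FPKM within 1.38e-05. FPKM shares out the reads of a library, so a group of abundant transcripts in one library lowers all other values there. A per-gene value also adds up all isoforms and includes exons outside a floxed region.

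The table holds 15967 rows, and 2 of them (Nppa and Myh6) have a status of HIDATA, under which the Cre value is listed at 0 and the comparison was not completed. These were treated as missing, which leaves 15965 genes. Before the data were examined it had been planned to keep such genes, and that setting is among the alternatives. In the remaining rows no value was 0 and the larger of the 2 values was at least 0.164 FPKM. FPKM summed to 497407 in the control library and 485189 in the Cre library, with medians of 8.27 and 7.13. The 10 highest genes took 6.38% and 10.2% of these sums. Spreadsheet software had turned 21 symbols into dates, and all 21 were restored from the RefSeq accession in the same row with an NCBI table for GRCm38, used for names only. No symbol was repeated, so no rows were summed. In 2208 rows the locus is shared with another row, so genes there can share reads, as can near-identical copies such as the alpha globin genes and the secretoglobin and H2-T families. Strand use is not stated, so Xist cannot be separated from its antisense partner.

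Read depth is unknown. Its ratio between libraries can be read from weak genes. The most frequent ratio of Cre to control FPKM was 0.824, in 32 genes (log2 values equal to 4 decimals), with 34 genes 1 log2 unit above it and 18 genes 1 unit below it, within 0.001. Read numbers in the ratios 1 to 1, 2 to 1 and 1 to 2 would give these steps if 1 read was worth 0.824 times as much FPKM in the Cre library as in the control, a relative depth of 1.21 for the Cre library over the control. The counts of genes at these steps were taken with unequal tolerances and do not settle which step is 1 to 1, so this depth is tentative. No absolute count follows from these ratios, so no counting interval is given. The deposited q-values fit a correction over 16046 tests with 104 calls, so 81 tested genes and 14 calls were not analysed here.

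With 1 library per genotype no test was run. Log2 ratios of FPKM + 1 (a pseudocount of 1) were computed for genes with a mean of at least 1 FPKM, leaving out 29 small-RNA genes, and genes were counted as higher or lower at a ratio of at least 2-fold. For each of 34 gene lists, fixed from textbook knowledge before the data were examined, the median ratio of the measured members was placed among 10000 random lists of the same size, each member being replaced by a gene from the same one of 20 bins of mean expression. A list stands apart below the 2.5 or above the 97.5 percentile. The 2 lists of sex-linked genes are given as values only. The genes named were fixed by rule: Arid1a, 18 genes of the node and working myocardium (1 of them is not reported here), up to 4 members with the largest absolute ratio per list, and the 10 highest and 10 lowest ratios among genes with a mean of at least 5 FPKM, without unnamed gene models. A further 6 lists (thymic epithelium, immature thymocytes, ciliated, secretory and alveolar lung cells, and mast cells) were written after values had been seen and appear only in the closing observations. Transcript lengths came from GENCODE M21, by RefSeq accession or else the longest transcript of the symbol, and were found for 99.3% of genes.

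Alternatives were pseudocounts of 0.1 and 5, no minimum or a minimum of 5 FPKM, ratios centred on their median, scaling to the same upper quartile or to an equal sum (TPM), size rules of 1.5-fold and 3-fold, small-RNA genes kept, the highest row per symbol, unfinished comparisons kept, random lists without matching, list means, and a stricter threshold on the authors' deposited q-values. Centring on 4 tissue lists and matching on transcript length were added after seeing the data. The procedure was tested on simulated data for this comparison with 13419 genes, whose unchanged ratios were normal with an SD of 0.666, set from the observed quartiles. The observed ratios were skewed, with 0.05 and 0.95 quantiles of -1.72 and 1.08, which the simulation did not copy. The size rule found 92.5% of 40 genes above 5 FPKM raised by 2.5 log2 units and 85.0% of 40 raised by 1.5, and all of 37 genes lowered by 2.5 and 63.2% of 38 lowered by 1.5. It also counted 8.59% of unchanged genes. Of 200 unchanged lists of 20 genes 5.5% stood apart, as did 38.5% of lists shifted by 0.25 and 85.0% of lists shifted by 0.5 log2 units. Simulated genes were independent and their lists random, so the 5.5% was set by design. These shares do not carry over to real lists, whose genes move together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.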

Results

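Gene expression was measured by sequencing of poly-A RNA from the sinoatrial node (the region of the right atrium that sets the heart rhythm) of mice 3 weeks after birth. The mice carried floxed alleles of Baf250a, the gene with the symbol Arid1a, which encodes a subunit of the BAF chromatin remodelling complex. In the Cre group the mice also carried Hcn4CreERT2, a Cre recombinase that is driven from the Hcn4 gene of pacemaker cells and becomes active after tamoxifen. The comparison described here set the library taken 6 days after tamoxifen from floxed mice with Hcn4CreERT2 (the Cre library) against the day-6 control library from floxed mice without Cre. It bears on the question named in the series title, whether Baf250a represses the Nkx2-5-directed contractile programme in the sinoatrial node. There was 1 library per genotype, so no difference below has a replicate check and no test of the genotypes was possible. The 5 libraries of the time series (a control and 16, 20, 24 and 48 h after tamoxifen) were not analysed here. Expression is given as FPKM, which summed to 497407 over genes in the control library and 485189 in the Cre library, and the read depth behind it is unknown. Log2 ratios are of FPKM + 1, Cre over control, which understates the change of weakly expressed genes. A gene was counted as higher or lower when it differed at least 2-fold on that scale.

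Arid1a, the floxed gene, was lower in the Cre library, at 12.3 FPKM against 34.9 FPKM in the control library, a log2 ratio of -1.43. In the authors' deposited table this difference had a p-value of 0.0603 and a q-value of 0.838. Arid1a (NM_001080819) lies on chromosome 4 of mm9 from 133234922 to 133309526, and its FPKM also covers exons outside the floxed part, so the value is a limited check of the deletion. Of the other 22 measured BAF subunits 5 were at least 2-fold lower and 0 were higher, and 3 lay above equal expression. Smarcd2 had 73.1 FPKM in the control and 23.0 FPKM in the Cre library. Smarca4, an ATPase of the complex, had 34.0 and 11.1 FPKM, and Arid2 had 27.2 and 8.79 FPKM. The median log2 ratio of the list, Arid1a included, was -0.51, at the 1.09 percentile of random gene lists matched on expression, although its mean did not stand apart. Histone deacetylases and corepressors had a median of -0.49 (1.74 percentile), again with a mean that did not stand apart, and 2 of 19 were lower. These were Hdac7, at 76.3 FPKM in the control and 17.7 FPKM in the Cre library, and Hdac1, at 93.6 and 28.7 FPKM. Hdac3 had 34.9 and 28.0 FPKM, a log2 ratio of -0.31. These lists differed in the same direction as the T cell and cell cycle genes described below.

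Across 13410 genes with a mean of at least 1 FPKM, 815 (6.08%) were at least 2-fold higher in the Cre library and 1396 (10.4%) were lower, so that 36.9% of these differences were towards the Cre library. With both libraries set to the same upper quartile the split turned to 1304 higher and 1085 lower, or 54.6% higher. A pseudocount of 5 gave 238 higher and 804 lower (22.8% higher), and centring of the ratios on the fibroblast, endothelial, adipocyte and epicardium lists (the tissue-list centring, added after seeing the data) gave 324 and 2919 (9.99%). The upper-quartile scaling moved the median log2 ratio of all genes from -0.07 to 0.13. Without it the quartiles were -0.52 and 0.38. Across genes, which are not independent replicates, log2(FPKM + 1) of the 2 libraries had a Pearson correlation of 0.857 and a Spearman correlation of 0.832. The authors' deposited table called 90 of the genes analysed here significant, 88 of them lower in the Cre library and 2 higher. A test on 2 libraries compares those libraries and not the genotypes. It also left uncalled Eif2s3y, at 85.8 FPKM in the control and 0.118 FPKM in the Cre library, and Sftpc, at 0.248 and 90.5 FPKM. A missing call is therefore not read here as equal expression. The genes called higher in the authors' deposited table were Xist and Bpifa1, named here after their values were seen. None of the 110 genes with a value in the pacemaker, contractile, atrial, transcription factor and channel lists was called in the authors' deposited table, where their smallest q-value was 0.164.

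**Figure D1:**
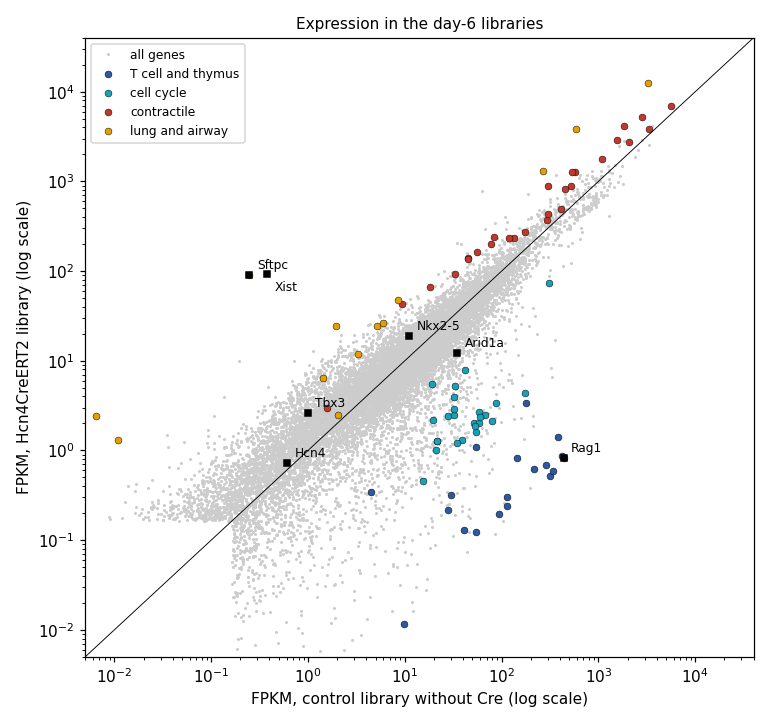
FPKM of each gene in the control library without Cre (horizontal, log scale) and in the Hcn4CreERT2 library (vertical, log scale), with 4 gene lists in colour, named genes as black squares and the line of equal expression. T cell and cell cycle genes lie below the line, with Rag1 at 436 FPKM in the control and 0.832 FPKM in the Cre library, while the contractile genes lie above it.

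The core regulators of pacemaker cells were weakly expressed in both libraries, and Hcn4, Isl1 and Shox2 differed little between them before any centring. Hcn4, which encodes the main pacemaker channel, had 0.605 FPKM in the control and 0.719 FPKM in the Cre library (mm9 chromosome 9, 58671318 to 58708762). Its mean was below the minimum of 1 FPKM, so it is not among the measured genes of its list. The transcription factors Isl1 and Shox2 had 1.69 and 1.20 FPKM in the control and 2.02 and 1.26 FPKM in the Cre library. Tbx3, a repressor of working-muscle genes in the node, had 0.996 and 2.59 FPKM, a log2 ratio of 0.85 that passed the size rule only with a pseudocount of 0.1 or in TPM. In the whole list of pacemaker and conduction regulators 5 of 20 measured genes were higher and 0 were lower. Kcne1, a potassium channel subunit, had 0.711 FPKM in the control and 9.96 FPKM in the Cre library, Popdc2 had 43.8 and 111 FPKM, Kcnj5 had 15.4 and 32.2 FPKM, and Cacna1g, a T-type calcium channel, had 1.57 and 4.37 FPKM. The median log2 ratio of the list was 0.51 (99.58 percentile), or 0.10 with the tissue-list centring. It no longer stood apart with weakly expressed genes kept (95.7 percentile) or in TPM (also 95.7).

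Cardiac transcription factors were higher as a group, as were the smooth muscle, fibroblast, endothelial, adipocyte and lung lists given below. Nkx2-5, the factor named in the series title, had 11.0 FPKM in the control and 18.8 FPKM in the Cre library, a log2 ratio of 0.72 that did not pass the size rule (mm9 chromosome 17, 26975609 to 26978510). Tbx5, Gata4 and Gata6 had 11.0, 9.40 and 15.0 FPKM in the control and 22.2, 19.1 and 29.6 FPKM in the Cre library, with log2 ratios of 0.95, 0.95 and 0.94 just short of the rule, which all of them passed with the same upper quartile. Of 22 measured factors 6 were at least 2-fold higher and 0 were lower. Myocd, a coactivator of muscle genes, had 1.44 and 6.97 FPKM, Irx3 had 1.31 and 5.55 FPKM, and Irx5 had 1.14 and 3.69 FPKM. The list's median was 0.83 (above all random lists), or 0.42 with the tissue-list centring.

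Contractile genes of the working myocardium lay above equal expression in 27 of 27 measured members, with 12 at least 2-fold higher and 0 lower. Ttn, the giant spring protein of the sarcomere, had 9.31 FPKM in the control and 43.0 FPKM in the Cre library. Ryr2, the calcium release channel, had 18.0 and 67.0 FPKM, Myh7 had 45.2 and 139.8 FPKM, and Myom1 had 45.2 and 138 FPKM. The median log2 ratio was 0.91 (quartiles 0.65 to 1.46), above all random lists, and 0.50 with the tissue-list centring. Within this list the difference varied with transcript length. The 9 genes with the shortest transcripts had a median log2 ratio of 0.72 and the 9 with the longest 1.53, and Spearman's rho across the 27 genes was 0.692. It was 0.724 across 25 fibroblast and matrix genes, 0.480 across 43 oxidative phosphorylation genes and 0.389 in both the atrial and the stress list. Among the lists where rho was negative were cardiac transcription factors (-0.17), ventricular genes (-0.12), BAF subunits (-0.38), lung genes (-0.38) and 11 neuron genes (-0.682). Across all 13353 genes with a length rho was 0.03. Ventricular genes had a median of 0.95 (above all random lists), with 4 of 8 higher, among them Myl3 at 304 and 884 FPKM and Myl2 at 572 and 1280.2 FPKM. Fetal and hypertrophic stress genes had a median of 0.64 (99.98 percentile) and 5 of 15 were higher, including Xirp1 at 3.81 and 14.7 FPKM. The lists share members, and lists of other tissues, given below, were also higher in the Cre library.

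Atrial working-muscle genes had a median of 0.67 (99.96 percentile) and 3 of 15 were higher. Nppb had 63.2 FPKM in the control and 153 FPKM in the Cre library. The gap junction genes Gja5 and Gja1 had 8.46 and 71.2 FPKM in the control and 12.7 and 114 FPKM in the Cre library, below the size rule. Nppa and Myh6 had 12217 and 628 FPKM in the control library. The authors' deposited table marks their comparison as not completed and lists the Cre library at 0, which is not read here as a level. Among ion channel and calcium handling genes 11 of 30 were higher and 1 was lower, with a median of 0.81 (above all random lists). Slc8a1, the sodium-calcium exchanger, had 6.09 and 24.4 FPKM, and the L-type calcium channel gene Cacna1c had 2.93 and 11.7 FPKM. Scn4b was the gene that was lower, at 3.65 and 0.172 FPKM, in the same direction as the T cell and cell cycle genes described below. Which cells its transcripts came from was not tested. Kcnj3 had 15.7 and 28.4 FPKM, a log2 ratio of 0.81.

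**Figure D2:**
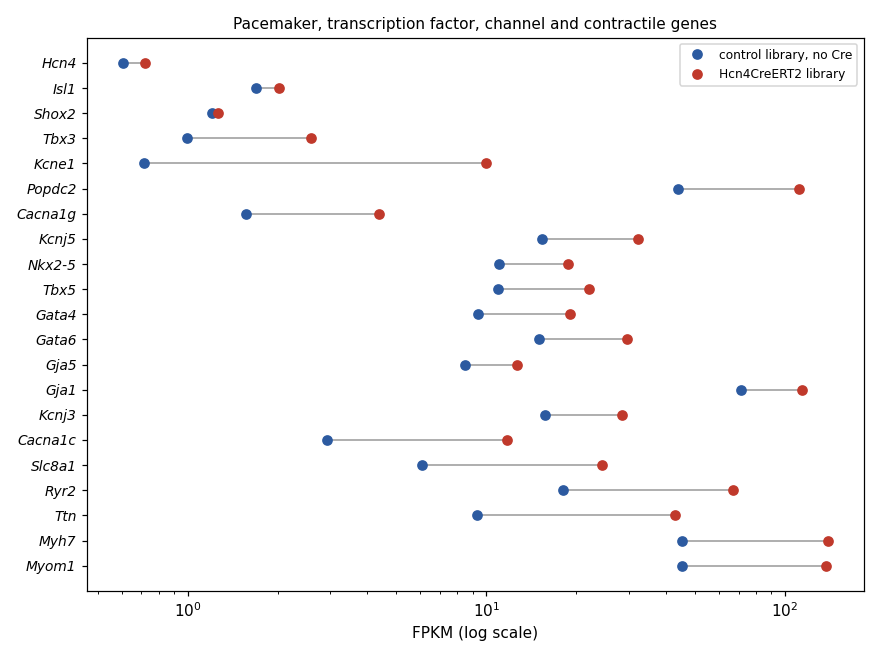
FPKM (log scale) of pacemaker, transcription factor, channel and contractile genes in the control library without Cre (blue) and the Hcn4CreERT2 library (red), each point a single library. Hcn4, Isl1 and Shox2 lie close together and low in both libraries, while Ryr2 lies at 18.0 FPKM in the control and 67.0 FPKM in the Cre library.

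Fatty acid oxidation genes had a median log2 ratio of 0.48 (99.99 percentile), or 0.07 with the tissue-list centring, with 2 of 24 at least 2-fold higher. These were Cpt1b, which brings fatty acids into mitochondria of muscle, at 69.9 and 152 FPKM, and the regulator Ppara at 6.47 and 14.2 FPKM. None of 43 oxidative phosphorylation genes passed the size rule, with a median of 0.25 (97.8 percentile) that became -0.16 with the tissue-list centring. It no longer stood apart with a minimum of 5 FPKM (95.9 percentile) or with the same upper quartile (97.1). Glycolysis genes had a median of 0.24 and did not stand apart (95.4 percentile). Cytosolic ribosomal protein genes were below equal expression in 39 of 39 members, with a median of -0.54 (below all random lists) and none past the size rule, in the same direction as the T cell and cell cycle genes described below. Rpl32 had 947 FPKM in the control and 524 FPKM in the Cre library.

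T cell and thymus genes had the lowest ratios. All 19 measured T cell and thymus genes were lower in the Cre library, with a median log2 ratio of -6.31. Rag1, which cuts antigen receptor genes in immature lymphocytes, had 436 FPKM in the control and 0.832 FPKM in the Cre library. Dntt, which adds bases at those cuts, had 343 and 0.586 FPKM, Cd8a had 314 and 0.521 FPKM, and Cd8b1 had 417 and 0.864 FPKM. All 25 cell cycle genes were lower too, with a median of -3.51. Top2a had 174 and 4.37 FPKM, and Mki67 had 80.5 and 2.12 FPKM. Both medians were below all of the random lists. The authors' deposited table called 9 genes of the T cell list and 10 of the cell cycle list significant. The 10 genes with the lowest ratios at a mean of at least 5 FPKM were Rag1, Cd8b1, Dntt, Cd8a, Lck, Tcf7, Prss16, Cd3g, Cd3e and Sh2d1a, between -7.90 and -6.49. Prss16, a protease of thymic epithelium, had 198 FPKM in the control and 0.381 FPKM in the Cre library, and Lck, a kinase of T cells, had 290.2 and 0.682 FPKM.

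Lung and airway genes were the highest list, with 11 of 12 measured members at least 2-fold higher and a median of 2.003 (above all random lists). Sftpc, a surfactant protein of the alveoli, had 0.248 FPKM in the control and 90.5 FPKM in the Cre library, Sftpb had 1.95 and 24.5 FPKM, and Scgb3a1, a secretory protein of airway epithelium, had 580.1 and 3804 FPKM. The 10 genes with the highest ratios were Sftpc, Xist, Bpifa1, Gbp1, Sftpb, Scgb3a1, Tpsab1, Kcne1, Spata18 and Ltf, between 6.20 and 2.51. Bpifa1, an airway secretory protein, had 62.0 and 775 FPKM, and Ltf, lactoferrin, had 34.9 and 204 FPKM. Gbp1 and Tpsab1 have close copies in the genome, so their values are uncertain.

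Sex-linked genes separated the libraries. Xist, expressed from the inactive X chromosome of females, had 0.379 FPKM in the control and 93.2 FPKM in the Cre library. The Y-linked genes Eif2s3y and Ddx3y had 85.8 and 43.4 FPKM in the control and 0.118 and 0.0739 FPKM in the Cre library, and Uty and Kdm5d were likewise lower, at log2 ratios of -4.11 and -3.70. The labels do not give the sex of the animals. By these genes the libraries differ in sex, so sex cannot be separated from genotype here.

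Genes of the other cell types of the tissue were mostly somewhat higher in the Cre library. Smooth muscle and pericyte genes had a median of 0.91 (above all random lists) with 5 of 14 higher, led by Rgs5 at 25.4 and 99.3 FPKM. Fibroblast and matrix genes had a median of 0.42 (99.96 percentile), with 2 of 25 higher, Pdgfra at 14.1 and 34.7 FPKM and Col6a3 at 10.2 and 24.9 FPKM, and 1 lower. The lower one was Thy1, which T cells also express, at 329 and 6.62 FPKM. Endothelial genes had a median of 0.41 (99.91 percentile) and none of 19 passed the size rule. This median became 0.00 with the tissue-list centring, of which it is a part. Adipocyte genes had a median of 0.51 (99.99 percentile) with 1 of 16 higher and 2 lower. Plin4 had 23.5 and 67.5 FPKM, and Elovl3 and Dio2 had 13.0 and 10.4 FPKM in the control and 4.90 and 4.46 FPKM in the Cre library. Neuron and autonomic ganglion genes had a median of 0.64 (98.7 percentile) with 3 of 11 higher, led by Npy at 0.963 and 7.06 FPKM. Their call was lost with a pseudocount of 0.1 (97.0 percentile) or a minimum of 5 FPKM (95.7). Red blood cell genes had a median of -0.80 over 5 genes (2.18 percentile), with Alas2 at 27.5 and 14.8 FPKM, and 6 of the other settings ended this call. Medians that did not stand apart were 0.21 for epicardium and mesothelium, 0.40 for Schwann cells, -0.09 for macrophages, 0.51 for B cells, 0.54 for skeletal muscle and 0.02 for chondrocyte and valve genes. In the macrophage list Ptprc, which all white blood cells express, had 179 and 4.52 FPKM.

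Among signalling and stress lists, clock genes had a median of 0.76 (99.99 percentile) with members on both sides. Nr1d1 had 22.6 FPKM in the control and 49.4 FPKM in the Cre library and Per3 had 8.80 and 18.9 FPKM, while Arntl, the partner of Clock, had 17.1 and 4.01 FPKM and Cry1 had 13.6 and 5.59 FPKM. The Notch, Wnt, Bmp and Tgf-beta list had a median of 0.35 (99.73 percentile), which became -0.06 with the tissue-list centring. Its lowest member was Lef1, also a T cell factor, at 27.7 and 0.218 FPKM, and Id4 and Hes1 were higher, at 2.81 and 9.46 FPKM in the control and 7.80 and 21.9 FPKM in the Cre library. For p53 and apoptosis genes the median was -0.44 (1.26 percentile) and 5 of 20 were lower, among them Trp53inp1 at 209 and 38.5 FPKM. That call was lost in 3 other settings, and the list differed in the same direction as the T cell and cell cycle genes. Medians of 0.02 for immediate early genes, 0.22 for heat shock and unfolded protein genes and -0.29 for interferon response genes did not stand apart, and the mean of the immediate early list had the opposite sign (-0.24). Among all lists that did not stand apart, the medians of glycolysis, Schwann cell, epicardium, chondrocyte, immediate early and heat shock genes turned negative with the tissue-list centring, and that of macrophages turned positive (0.13) with the same upper quartile. In these lists Btg2 had 108 and 12.8 FPKM, Hspb1 had 89.0 and 237 FPKM, and Cxcl10 had 4.82 and 0.449 FPKM. That centring also gave 0.54 for ventricular, 0.23 for stress, 0.27 for atrial, 0.40 for channel, 0.50 for smooth muscle, 0.01 for fibroblast, 0.10 for adipocyte, 0.23 for neuron, 0.35 for clock and 1.59 for lung genes, and -0.92 for BAF, -0.90 for histone deacetylase, -0.95 for ribosomal, -1.21 for red blood cell, -0.85 for p53, -3.92 for cell cycle and -6.71 for T cell genes. Altogether 24 of 34 lists stood apart, 17 higher and 7 lower, where 1.7 would be so by chance if lists were drawn at random. Genes of one tissue move together, so these percentiles describe the libraries and carry no error of the genotypes.

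**Figure D3:**
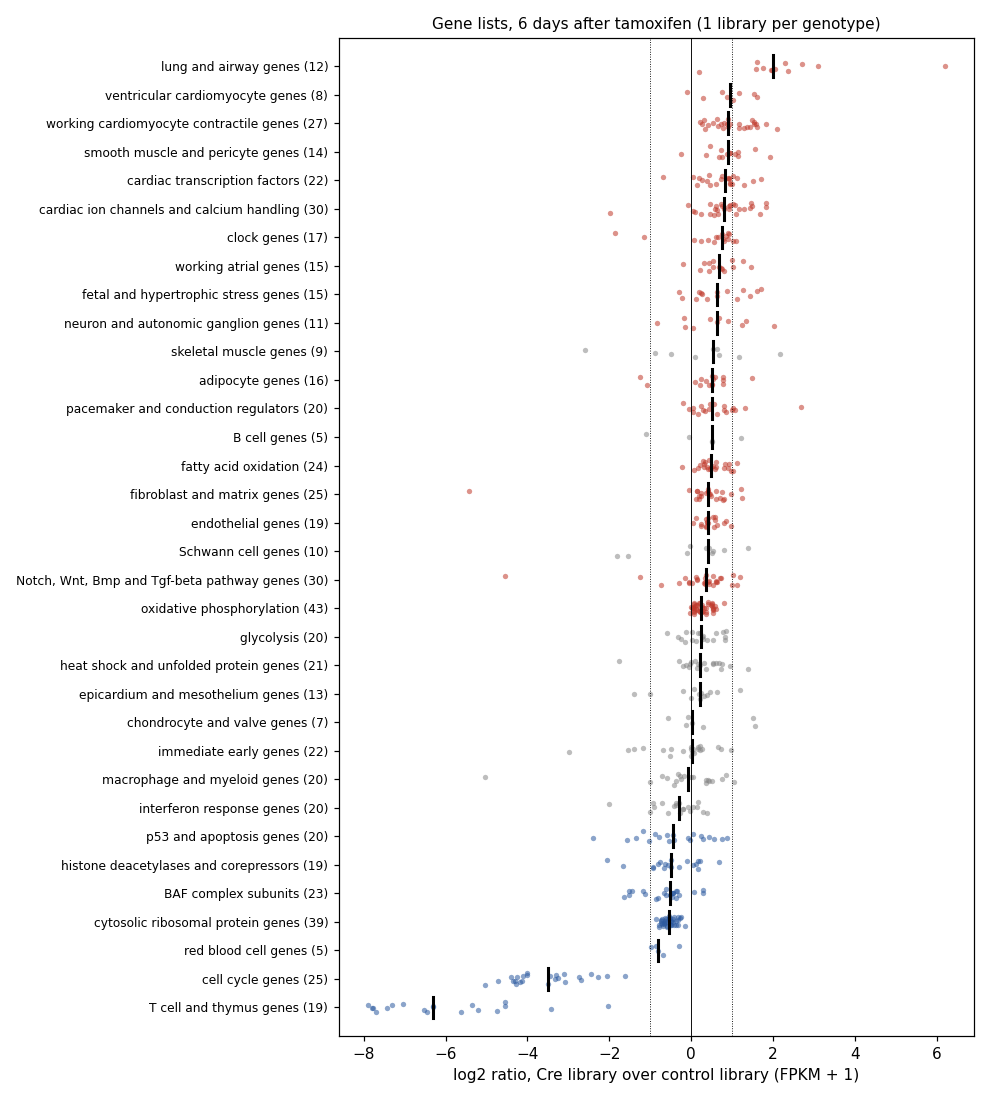
Log2 ratio of FPKM + 1, Cre library over control library (horizontal), of each measured gene (points) in 34 gene lists, with the number of genes in brackets and the median as a black bar. Red and blue lists stood apart above or below matched random lists, grey lists did not, and dotted lines mark the 2-fold size rule. The T cell list has a median of -6.31 and the contractile list one of 0.91.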

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

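Of 373 values of the 34 list percentiles under other settings, 352 stayed on the same side of the limits and none crossed to the opposite side. Centring the ratios on their median or on the 4 tissue lists subtracts the same constant from every gene and cannot change a percentile. Those values stayed the same by construction and are no sign of stability. The contractile, atrial, ventricular, transcription factor, channel, lung, T cell and cell cycle lists stood apart in the same direction under every setting run. Calls that were lost concerned the pacemaker list with no filter (95.7) or in TPM (95.7), the BAF (3.75) and histone deacetylase (10.3) lists as means, oxidative phosphorylation with a minimum of 5 FPKM (95.9) or the same upper quartile (97.1), and neurons with a pseudocount of 0.1 (97.0) or a minimum of 5 FPKM (95.7). Red blood cell genes lost theirs with a pseudocount of 0.1 (2.67), a minimum of 5 FPKM (3.14), TPM (3.24), no matching (2.5), list means (11.8) or matching on length, added after seeing the data (5.68). The p53 list lost its call with a pseudocount of 5 (3.38), a minimum of 5 FPKM (4.72) or list means (9.59). Calls were gained by Schwann cells without a filter (97.8), skeletal muscle with the same upper quartile (97.7) or no matching (98.7), and heat shock genes as a mean (98.2). The cause was not tested for any of these. Counts of genes moved more. Higher genes numbered 1262 with a pseudocount of 0.1, 238 with one of 5, 449 from 5 FPKM, 1304 with the same upper quartile, 324 with ratios centred on the 4 tissue lists (added after seeing the data), 2227 at 1.5-fold and 209 at 3-fold. Lower genes numbered 804 with a pseudocount of 5, 2919 with that centring, 2946 at 1.5-fold and 744 at 3-fold. The share of higher genes was 36.9% in the main count, 54.6% with the same upper quartile, 22.8% with a pseudocount of 5, 21.9% at 3-fold and 9.99% with that centring. The median of all genes was 0.13 with the same upper quartile and -0.48 with that centring, by construction of these scalings. Keeping the unfinished comparisons as 0 gave 1398 lower genes, and keeping the highest row per symbol changed nothing because no symbol was repeated. None of the authors' deposited calls had a q-value of at most 0.01 (0 genes), the smallest being 0.0149. Arid1a stayed at least 2-fold lower in every setting run for it, and none of the 159 named genes with a ratio changed sign after passing the size rule. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. Unknown depth leaves the counting error of weak genes open.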

Other observations

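The tests in this part were chosen after the values had been seen, except the one across all genes on transcript length. The test of dilution by spread replaced the difference from the tissue lists, also given below, after that difference had been seen, and its form without length trends was added after the plain form had been seen. The lists of lung, mast and thymus cell types used here, and the genes named from them, were also chosen after the values were seen, so their direction is a description and not independent evidence.

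Genes of multiciliated airway cells were expressed in both libraries and were higher in the Cre library in 13 of 14 measured members, with a narrow range of log2 ratios (quartiles 1.97 to 2.13, median 2.02). Foxj1, the regulator of motile cilia, had 5.96 FPKM in the control and 26.2 FPKM in the Cre library, Dynlrb2 had 5.37 and 32.3 FPKM, and Rsph1 had 4.11 and 19.8 FPKM. The exception was the tubulin gene Tubb2c, at 167 and 203 FPKM. Secretory airway genes were higher in 10 of 10 members, with a median of 2.19. Scgb1a1, the main club cell secretory protein, had 3261 FPKM in the control and 12533 FPKM in the Cre library and was the most abundant of these genes. Alveolar type 2 genes had a median of 2.26, and 5 of 6 were higher. Sftpc differed most of these, at a log2 ratio of 6.20. Foxj1, 3 secretory and 5 alveolar genes are also in the fixed lung and airway list. Mast cell genes, in no fixed list, had a median of 1.13 with 5 of 7 higher. Tpsab1 had 1.14 FPKM in the control and 12.9 FPKM in the Cre library, and Cma1 had 6.25 and 17.5 FPKM.

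T cell and cell cycle genes were lower in the Cre library. The values argue against T cells of the blood as the source, because Rag1, Rag2, Dntt and Ptcra, which mature blood T cells do not express, had a median of 199 FPKM in the control library and a median log2 ratio of -6.69, all 4 being also in the fixed T cell list. A candidate explanation is thymus tissue in the control dissection. Thymic epithelial genes, none of them in another list, had a median log2 ratio of -5.38 over 5 measured members, led by Prss16 at 198 and 0.381 FPKM, Ccl25 at 161 and 2.29 FPKM and Tbata at 134 and 2.23 FPKM. A lowering of cell cycle genes in heart cells after Arid1a deletion stays open, since the cell cycle median of -3.51 was measured beside dividing thymocytes and the 2 sources cannot be told apart.

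Heart muscle genes were higher in the Cre library. Loss of long transcripts from the control library as the whole cause was argued against, since Spearman's rho of length and log2 ratio was -0.0076 across 9296 genes outside the lists (range -0.03 to 0.01), although a slope of 0.11 per doubling of length (range 0.01 to 0.22) was present in the fibroblast, endothelial, adipocyte and epicardium lists. Dilution of the control by thymus RNA as the whole cause was examined by spread, since a tissue without contractile transcripts lowers all of them by the same factor. Their interquartile width of log2 ratios exceeded that of oxidative phosphorylation genes by 0.44 (95% range over resampled genes 0.11 to 0.79). With the length trend of each list taken out the excess was 0.24 (range -0.008 to 0.42). The width of the oxidative phosphorylation list is an assumed reference. Contractile genes span a wide range of expression, from Acta1 at 1.57 FPKM to Myl7 at 5603 FPKM in the control. The test therefore cannot decide the question, and dilution, alone or together with a difference by length, stays open. The 87 genes of the contractile, atrial, transcription factor and channel lists lay 0.40 above the 72 genes of the fibroblast, endothelial, adipocyte and epicardium lists (range 0.26 to 0.55), though thymus also holds such stroma. After adjustment for the slope of 0.11 they lay 0.43 above (range 0.24 to 0.55). The size of this gap depends on that choice of reference lists, made after seeing the data. Smooth muscle and pericyte genes, left out of it, had a median of 0.91, like the contractile genes (0.91), and neuron genes had 0.64. An effect of the Arid1a deletion and a larger share of heart muscle in the Cre dissection cannot be told apart with these values, because the lung and airway list, a sign of what was dissected, differed as well (median 2.003), and so did the sex-linked genes.

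Arid1a was lower in the Cre library, as a deletion would give. The other 22 BAF subunits, which were not targeted, had a median log2 ratio of -0.49 (1.45 percentile), and 5 of them were at least 2-fold lower, so thymus RNA in the control may account for part or all of the difference. The difference of Arid1a from that median was -0.94, but 3 of the other subunits lay lower still. Deletion in the Hcn4 cells therefore cannot be told apart from the tissue difference with these values, since Hcn4 itself had 0.605 and 0.719 FPKM and a per-gene value mixes all cells.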
